A study of Candida albicans with 6 samples.

How the data were processed

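RNA from *Candida albicans* SC5314, the wild-type reference strain of this yeast, was sequenced on an Illumina instrument in 6 libraries. Per the labels' protocols, RNA was extracted with a RiboPure-Yeast kit and libraries followed standard Illumina steps. The labels place 3 libraries in a control group without drug and 3 in a group treated with 4 µM compound 20. All 6 carry the time 3 hours, and the labels do not say from when it counts. Compound 20 is known here only by this name and by the code CHX45, which the names of its columns carry. The labels call the controls cells without drug, while the names of their columns carry DMSO, and whether they received DMSO is not stated.

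The authors deposited 1 table of FPKM, that is mapped fragments scaled for gene length and for the size of the library, with 2 decimals, for 5998 genes. HISAT2, StringTie 1.3.3 and Cufflinks 2.2.1 are named in the submitters' processing notes, without their roles. The genome build, the annotation and the strandedness of the libraries are not given in the sources used here. The table has no counts and no library totals, so the depth of each library is unknown and no counting interval could be given. Because the value of 1 fragment depends on gene length in FPKM, whole fragments could not be recovered. The ratio of genes below 1 FPKM between libraries gave only a weak reading of relative depth, with 27 to 120 genes per pair of libraries. The descriptions of all 3 control samples name the same column, so a control column cannot be tied to 1 sample, and control libraries are called by the number in their column. All 6 columns were used. Symbols came from the RefSeq annotation of assembly ASM18296v3, which matched all 5998 identifiers by locus tag and gave 2815 a symbol of their own. No coordinates were taken from it, since the build of the table is not named.

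Each comparison was fitted with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an intercept and the group as the only term, empirical Bayes moderation with a trend, and Benjamini-Hochberg adjustment. Genes with at least 1 FPKM in at least 3 libraries were tested. A log2 change is on the log2(FPKM + 1) scale, which understates the change of low genes, and its SE is the moderated standard error. A gene was called at an adjusted p below 0.05. Beside it stands the count that also changed at least 2-fold. Nothing states that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

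Before the data were examined, 33 gene lists were fixed, and the 32 with at least 5 tested genes were tested with camera, which sets a list against all other genes, with a preset correlation of 0.01. The camera test with an estimated correlation, and fry, which tests whether a list's genes move one way on balance, were the alternatives. With 6 libraries the estimated correlation rests on few residual degrees of freedom. Not passing that test is therefore weak evidence that a list did not move. Lists overlap, and their names describe the reason for grouping. The genes named in the text followed a rule fixed at the same time. It took the 10 highest and the 10 lowest log2 changes among genes with a symbol that passed the adjusted p, had all 3 treated libraries on one side of all 3 controls, and reached a mean of 10 FPKM in the higher group. It added, for each list past its test, up to 3 members with the largest change in the list's direction, and a fixed set of drug target, efflux, hypha, heat shock and reference genes. The rule named 72 genes, of which 70 passed the adjusted p. Genes named outside it, those of the last paragraph here included, were chosen after their values were seen.

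The alternatives changed 1 choice at a time. They were a pseudocount of 0.1 or 5, no filter or a filter at 10 FPKM in 3 libraries, scaling to the same total, scaling by the median ratio to the geometric mean, quantile normalization, moderation without the trend or with robust estimates, limma array weights, and leaving out each library in turn.

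The fit was tested on simulated data for the comparison of compound 20 with the control, over 5906 genes with 200 changed by known amounts. It called 41 of 67 genes changed by 0.5 on the log2 scale (61.2%), 65 of 67 changed by 1 (97.0%) and 66 of 66 changed by 2, together with 13 unchanged genes. The list test called the 1 list that was moved and 0 of the others at an adjusted p below 0.05. The simulated genes were drawn independently of each other and few of them moved. In the real data the ribosome biogenesis list, for example, had an estimated correlation of 0.16. The simulation therefore does not show how often the list test errs on correlated genes. Nor does it show how the gene test fares when most genes shift, as with the median log2 change of 0.59 in the real data.

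Some values are uncertain. The table gives 18 genes in 9 pairs identical values in all 6 libraries, among them TSA1 with TSA1B, and HSP12, NSA2 and ECM18 each with a gene without a symbol, so reads may have been shared within these pairs. VPS35, DHH1 and CAALFM_C601590WA are listed at 0 in all 3 compound 20 libraries, and CAALFM_C405860WA and CAALFM_C208350CA in all 3 controls. An exact 0 in such a table can be a failed estimate, so no fold is given for them.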

Results

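The transcriptome of *Candida albicans* SC5314 was measured by RNA sequencing in 3 control libraries without drug and in 3 libraries of cells treated with 4 µM compound 20. The comparison asks which transcripts differ between treated cells and controls. The labels describe the controls as without drug and their columns are named for DMSO, and whether they received DMSO is not stated. Values are the deposited FPKM, and the depth behind them is unknown. The FPKM of all genes summed to between 894302 and 895595 in the controls and to between 964454 and 976432 with compound 20. The median gene stood at 31.8 to 35.0 FPKM in the controls and at 47.0 to 49.9 FPKM with compound 20. The 10 most abundant genes of a library took 15.8% to 16.8% of the summed FPKM in the controls and 6.86% to 7.56% with compound 20. Libraries of 1 group ranked the genes almost alike, with Spearman's rho across genes of 0.994 to 0.995 over 6 pairs, and libraries of different groups did so less, with 0.738 to 0.747 over 9 pairs. The median coefficient of variation of a gene was 8.61% in the controls and 6.60% with compound 20.

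With compound 20, most tested genes of ribosome production, amino acid synthesis and DNA replication were higher. Most genes of glycolysis, of the use of other carbon sources, of the zinc, copper and iron lists and of oxidative stress defence were lower. These lists passed the camera test, with 8 of 24 iron and 9 of 36 oxidative stress genes going the other way, and 0 of the 32 lists tested passed it with an estimated correlation (smallest adjusted p = 0.175). Of 5906 genes tested with limma, 5018 (85.0%) passed the adjusted p. Of these, 3552 were higher and 1466 were lower with compound 20, and 70.8% of the called genes were higher. A change of at least 2-fold was also met by 2764 genes, 2130 higher and 634 lower. The 3 treated libraries lay wholly above or below the 3 controls for 5060 genes (85.7%), where chance gives 10% for a single gene. Separation was counted only as deposited, and a shift shared by most genes can add to it. The median log2 change of all tested genes was 0.59, so the balance of higher and lower genes depended on how the libraries were scaled. After median-ratio scaling, 5035 genes passed, 2517 higher and 2518 lower, and 49.99% of the called genes were higher. In the same direction under both scalings, 2517 genes were called higher and 1466 lower. A further 266 genes were called higher as deposited and lower after scaling. For this reason the log2 changes of named genes below are given relative to the median of 0.59 unless the text says otherwise, and an SE is that of the fitted change. Adjusted p-values test the change as deposited unless the call or test itself is said to follow a scaling. Those in brackets directly after counts of higher and lower genes are as deposited, also where the last counts are after scaling.

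**Figure D1:**
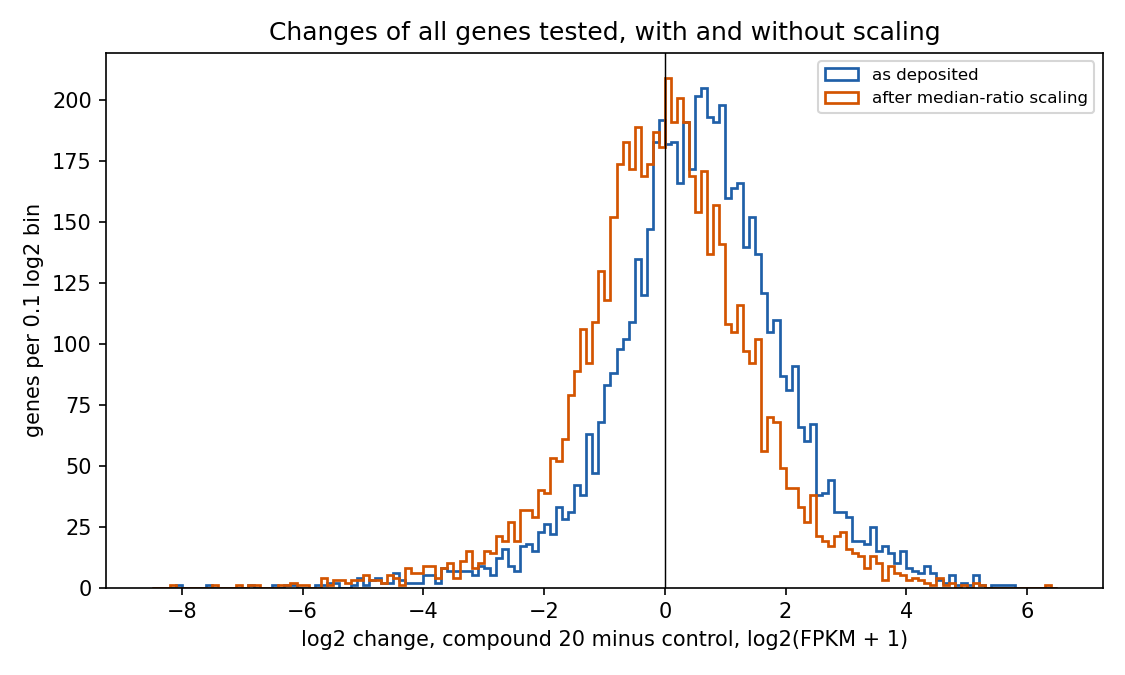
Histogram of the log2 change of each of the 5906 genes tested (x axis, compound 20 minus control on log2(FPKM + 1); y axis, genes per bin), as deposited in blue and after median-ratio scaling in orange. The deposited changes centre above 0, with a median of 0.59, and scaling by the median ratio moves that centre to near 0.

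Among the genes that the naming rule covers, SOD3 fell most. SOD3 (CAALFM_C700110WA), a manganese superoxide dismutase, stood at 3949 ± 231 FPKM in the controls and at 14.0 ± 0.611 FPKM with compound 20 (SD, n = 3). Its log2 change was -8.04 ± 0.071 as deposited (SE, adjusted p = 5.30e-14) and -8.63 relative to the median gene. ICL1 (CAALFM_C104500WA), the isocitrate lyase of the glyoxylate cycle, went from 2403 ± 175 to 11.8 ± 1.06 FPKM. The white-cell gene WH11 (CAALFM_C205180WA) went from 2095 ± 653 to 17.4 ± 6.57 FPKM and varied more between libraries than the others. FDH1, a formate dehydrogenase, changed by -7.04 ± 0.10. The reductase genes FRE7 and FRE30 changed by -6.86 ± 0.063 and -6.78 ± 0.10. The cell surface superoxide dismutase SOD4 changed by -6.36 ± 0.085, the aldose reductase GRE3 by -6.24 ± 0.067, the malate synthase MLS1 by -6.18 ± 0.092 and ASR1 by -6.12 ± 0.13. Adjusted p-values of these 9 genes lay between 1.10e-13 and 4.94e-10.

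The 10 largest rises that the rule selected include NOG1, NOC2, ENP1 and ENP2 of the fixed ribosome biogenesis list. NOG1 (CAALFM_C306030WA), a GTPase of large subunit assembly, rose from 8.92 ± 1.12 to 329.6 ± 11.8 FPKM (SD, n = 3). Its log2 change was 5.06 ± 0.094 as deposited (SE, adjusted p = 3.29e-12) and 4.48 relative to the median gene. NOC2 rose by 4.68 ± 0.10, ENP1 by 4.19 ± 0.11 and ENP2 by 4.17 ± 0.11. RLP24, which rose by 4.32 ± 0.16, and PES1, which rose by 4.11 ± 0.088, are in no fixed list. The highest rise among genes with a symbol that met the rule was that of MIS12 (CAALFM_CR00080WA), from 5.15 ± 0.645 to 337.5 ± 25.7 FPKM. Its log2 change was 5.78 ± 0.10 as deposited and 5.20 relative to the median gene. ECM331 rose by 5.08 ± 0.10, the serine and threonine deaminase gene CHA1 by 4.54 ± 0.085 and the aquaporin gene AQY1 by 4.28 ± 0.13. The adjusted p-values of these 10 genes lay between 1.77e-12 and 1.19e-10.

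**Figure D2:**
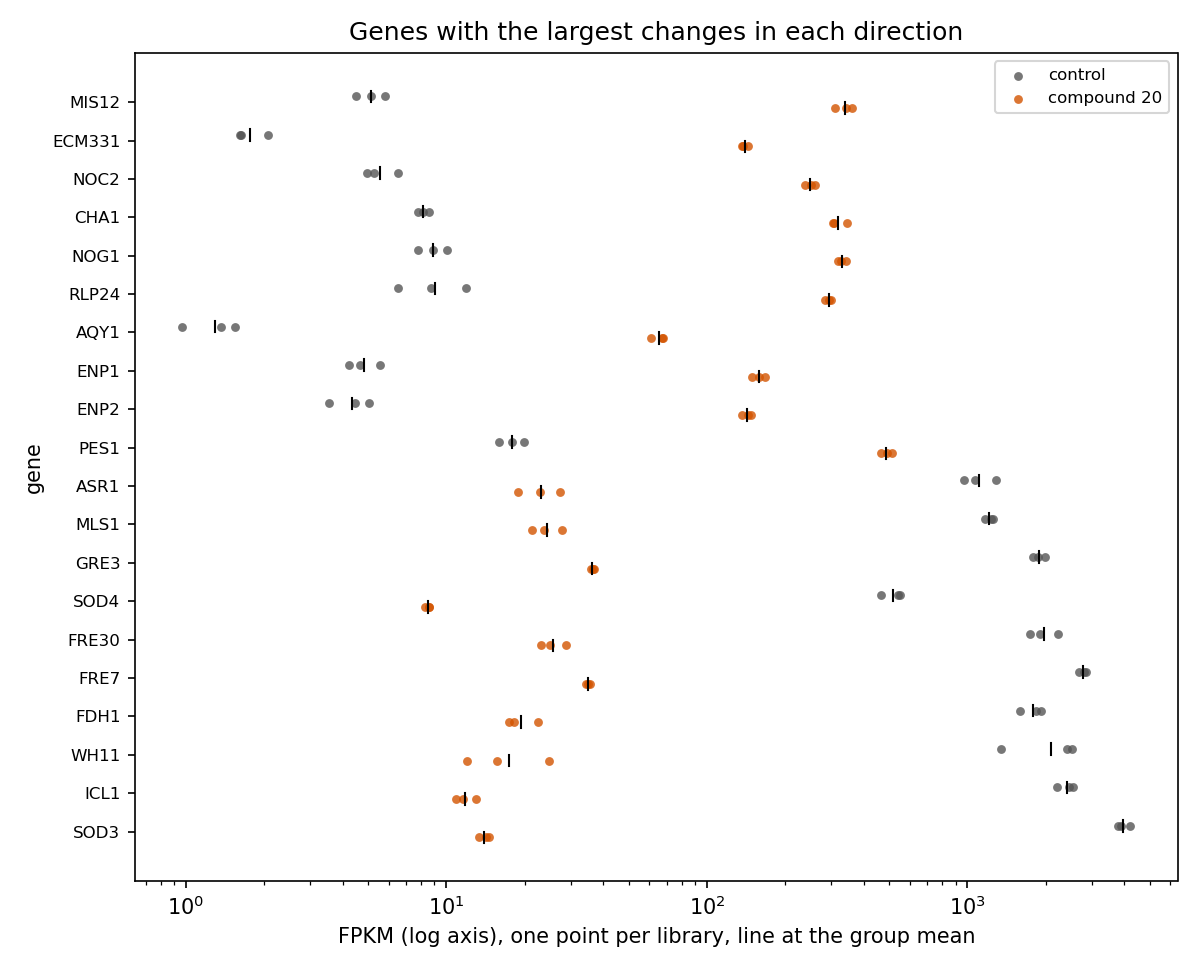
FPKM (x axis, log axis) of the 10 genes with the largest rises and the 10 with the largest falls that the naming rule selected (y axis), with 1 point per library, controls in grey and compound 20 in orange, and a line at each group mean. The naming rule admitted only genes whose 3 treated libraries all lie on one side of the 3 controls.

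Nearly all tested genes of ribosome production rose. All 65 ribosome biogenesis genes were higher with compound 20, and all 65 remained so after median-ratio scaling, with a median log2 change of 2.65 relative to all genes. The list passed the camera test (adjusted p = 4.58e-12), and not with an estimated correlation (adjusted p = 0.216). All 72 genes of the cytosolic ribosomal protein list were higher, 70 of them after scaling, with a median of 1.61 relative to all genes (adjusted p = 4.83e-11, and adjusted p = 0.216 with an estimated correlation). That list was drawn by symbols starting with RPL, RPS or RPP, so a gene of another function could be in it. RPS20 rose from 319.5 ± 10.1 to 2731 ± 139 FPKM, RPL8B from 369.9 ± 59.8 to 3008 ± 96.2 FPKM and RPS24 from 450.5 ± 60.5 to 3418 ± 316 FPKM (SD, n = 3). In the mitochondrial ribosome list, 16 of 18 genes rose and 1 fell, and 15 and 3 after scaling (adjusted p = 0.0103, and adjusted p = 0.558 with an estimated correlation). IMG2 rose by 3.20 ± 0.21, MRPL36 by 2.22 ± 0.12 and RSM22 by 1.96 ± 0.095, while MRP17, named after its value was seen, was the 1 that fell.

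Most genes of amino acid synthesis, DNA replication and protein folding were higher as well. Of 52 amino acid biosynthesis genes, 44 were higher and 6 lower, and 40 and 9 after scaling (adjusted p = 1.92e-04, and adjusted p = 0.312 with an estimated correlation). HIS7, of histidine synthesis, rose from 14.1 ± 1.52 to 311.9 ± 13.8 FPKM, the homocitrate synthase LYS22 of lysine synthesis from 44.4 ± 1.43 to 815.8 ± 25.3 FPKM, and ARO3 of aromatic amino acid synthesis from 56.9 ± 3.41 to 1022 ± 18.4 FPKM (SD, n = 3). Among the 6 lower genes, chosen after their values were seen, ARG1, ARG3 and ARG4 act in arginine synthesis, and their log2 changes before subtraction of the median were -1.95, -4.39 and -0.74. Of 26 histone and DNA replication genes, 23 rose and 2 fell, and 19 and 3 after scaling (adjusted p = 0.00777, and adjusted p = 0.312 with an estimated correlation). The ribonucleotide reductase gene RNR1 rose by 3.41 ± 0.091, the primase gene PRI2 by 2.67 ± 0.13 and the DNA polymerase gene POL1 by 2.24 ± 0.11. The genes that fell were RNR21 and RNR22, which also belong to ribonucleotide reductase and were named after their values were seen. In the list of endoplasmic reticulum stress and protein folding, 14 of 15 genes rose and 0 fell, and after scaling 11 rose and 3 fell (adjusted p = 0.0256, and adjusted p = 0.558 with an estimated correlation). Its call ended after median-ratio scaling (adjusted p = 0.0722), and its adjusted p with the preset correlation ran from 0.0101 to 0.0722 over the alternatives. Its largest rises were in PMT4 at 1.84 ± 0.090 and PMT1 at 1.20 ± 0.075, which add mannose to proteins, and in the chaperone gene JEM1 at 1.13 ± 0.12.

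Genes of sugar use were lower with compound 20. Of 20 glycolysis and fermentation genes, 17 were lower and 2 higher, and after scaling 19 were lower and 0 higher, with a median of -2.56 relative to all genes. The list passed the camera test (adjusted p = 2.93e-10), and not with an estimated correlation (adjusted p = 0.175). The pyruvate decarboxylase gene PDC11 went from 17508 ± 380 to 1150 ± 22.1 FPKM, the alcohol dehydrogenase gene ADH1 from 26697 ± 773 to 2448 ± 93.9 FPKM and the triose phosphate isomerase gene TPI1 from 4607 ± 234 to 459.8 ± 19.5 FPKM (SD, n = 3). Both genes that were higher, TYE7 and GAL4, encode transcription factors of the pathway and were named after their values were seen. TDH3, which was named after its value was seen, ADH1 and PDC11 together took 8.67% to 9.31% of the summed FPKM of a control library and 0.770% to 0.852% of a treated one. Of 17 hexose transporter genes, 13 were lower and 2 higher, and 14 and 2 after scaling (adjusted p = 7.62e-05, and adjusted p = 0.216 with an estimated correlation). HGT19 changed by -5.21 ± 0.11, HGT6 by -4.28 ± 0.069 and HGT10 by -3.40 ± 0.090, while HGT12 and HGT14, named after their values were seen, were the 2 that rose.

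Genes for using acetate and fatty acids were lower too. Of 15 genes of the glyoxylate cycle, gluconeogenesis and acetate use, 11 were lower and 3 higher, and 13 and 2 after scaling (adjusted p = 1.08e-05, and adjusted p = 0.175 with an estimated correlation). Besides ICL1 and MLS1, the dicarboxylate transporter gene JEN2 changed by -4.86 ± 0.16. The 3 higher genes, named after their values were seen, were CAT8, JEN1 and ACS2. Of 26 genes of fatty acid oxidation and the peroxisome, 20 were lower and 4 higher, and 23 and 1 after scaling (adjusted p = 4.92e-07, and adjusted p = 0.216 with an estimated correlation). FOX2 of fatty acid oxidation changed by -2.96 ± 0.084, the carnitine acetyltransferase gene CTN3 by -2.83 ± 0.12 and ECI1 by -2.40 ± 0.089. The higher genes, named after their values were seen, were PEX5, PEX7, FAA2-3 and POX18.

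Most zinc, copper and iron genes were lower. Of 9 zinc and copper homeostasis genes, 7 were lower and 2 higher, and the list median was -2.58 relative to all genes (adjusted p = 2.44e-04, and adjusted p = 0.342 with an estimated correlation). The copper transporter gene CTR1 (CAALFM_C600790CA) fell from 7426 ± 216 to 227.9 ± 7.23 FPKM (SD, n = 3). The secreted zinc-binding protein gene PRA1 changed by -5.33 ± 0.083 and the zinc transporter gene ZRT1 by -4.48 ± 0.094. The 2 higher genes, CTR2 and CUP2, were named after their values were seen and were no longer called higher after scaling. Of 24 iron acquisition genes, 15 were lower and 8 higher, and 17 and 5 after scaling (adjusted p = 9.61e-04, and adjusted p = 0.235 with an estimated correlation). CFL2, a ferric reductase gene, changed by -5.34 ± 0.066 and the multicopper oxidase gene FET31 by -3.59 ± 0.067. The 8 higher genes, named after their values were seen, were FTR2, FRE10, SIT1, HMX1, SFU1, FTR1, FET3 and FET34. The first 5 of these stayed higher after scaling. FTR2 rose from 31.8 ± 4.71 to 274.9 ± 16.1 FPKM.

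Oxidative stress defence and sulfur amino acid genes were mostly lower. Of 36 oxidative stress defence genes, 22 were lower and 9 higher, and 28 and 6 after scaling (adjusted p = 5.70e-07, and adjusted p = 0.175 with an estimated correlation). Besides SOD3 and SOD4, EBP1, an NADPH oxidoreductase, fell from 2881 ± 282 to 107.2 ± 2.22 FPKM (SD, n = 3). TSA1 and TSA1B of this list, named after their values were seen, carry identical values in the table and count as 2 of the lower genes. Of 18 sulfur amino acid genes, 12 were lower and 3 higher, and 15 and 0 after scaling (adjusted p = 6.40e-05, and adjusted p = 0.312 with an estimated correlation). The transcription factor gene CBF1 fell from 6058 ± 97.4 to 408.8 ± 9.95 FPKM, MET3 changed by -3.53 ± 0.11 and MET15 by -3.16 ± 0.092. The locus tag of CBF1, CAALFM_C406580WA, comes right after that of the more abundant PDC11, CAALFM_C406570CA. As deposited CBF1 fell 14.8-fold and PDC11 15.2-fold. Whether fragments of PDC11 were counted for CBF1 was not tested, and the strandedness of the libraries is not given. The higher genes, named after their values were seen, were STR2, MUP1 and ECM17.

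**Figure D3:**
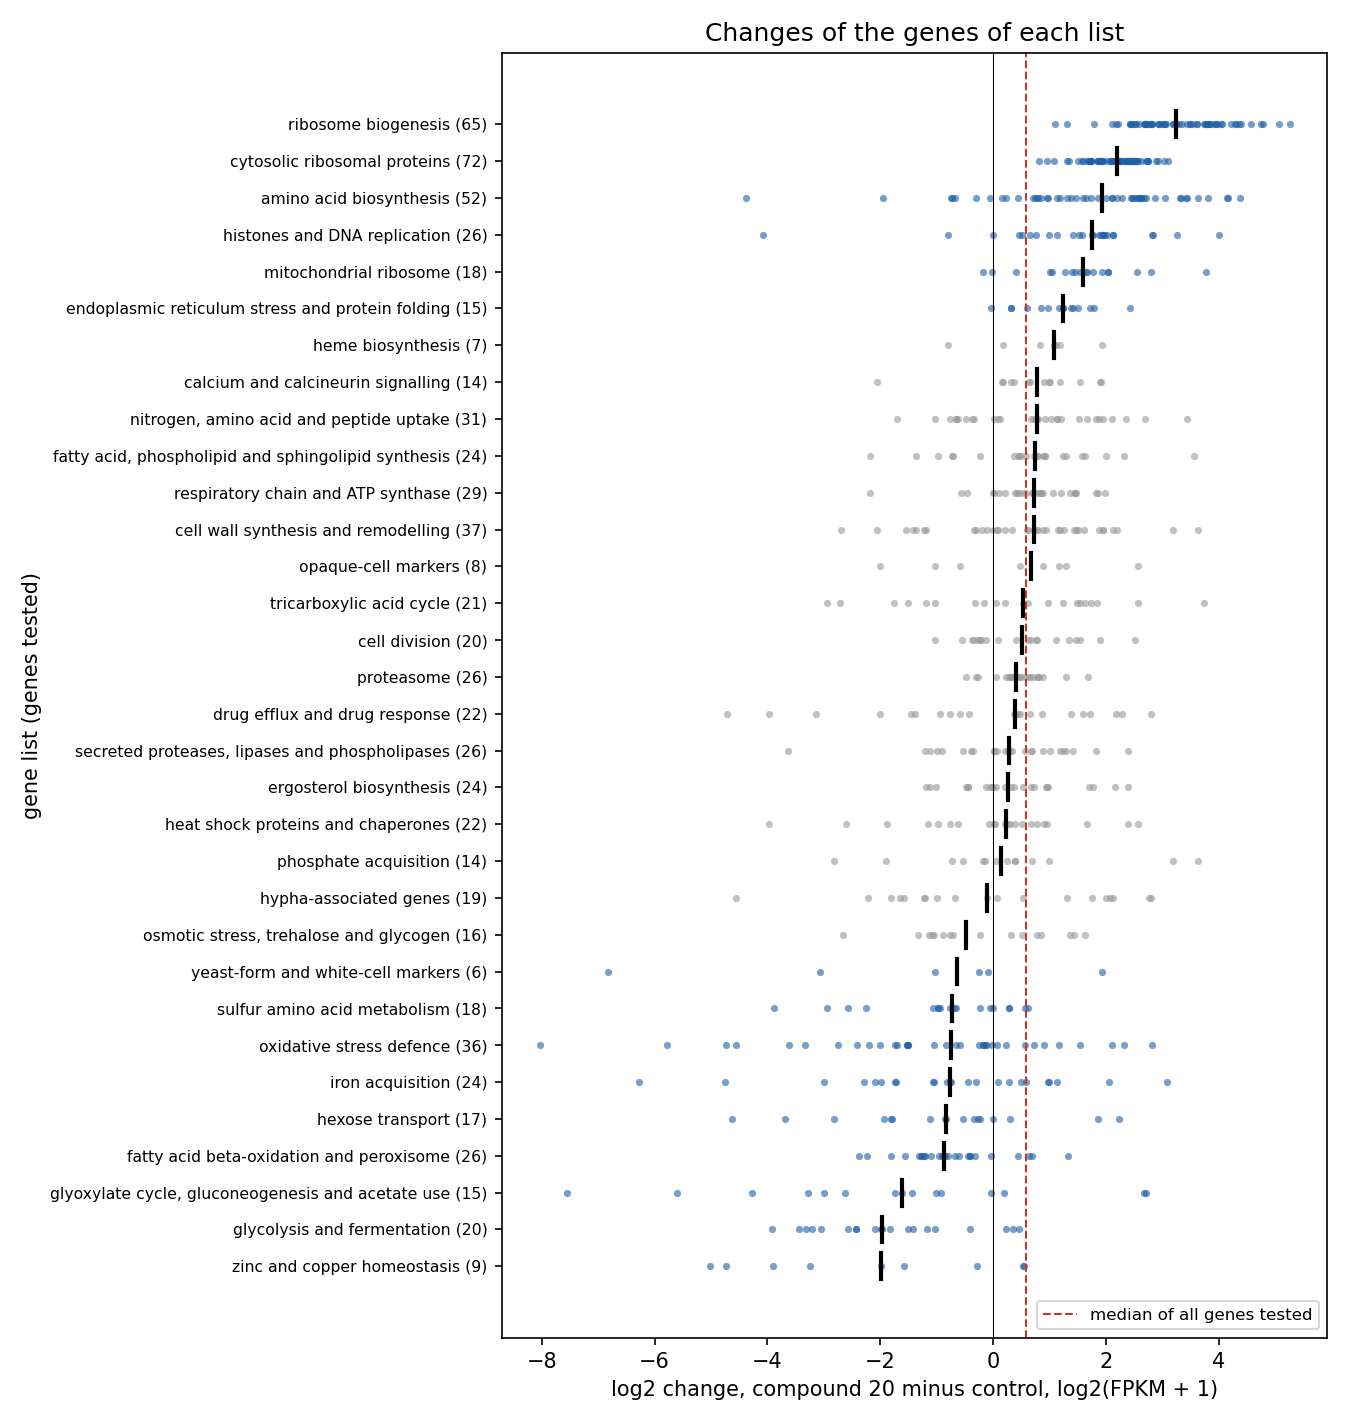
Log2 change of each gene (points; x axis, compound 20 minus control on log2(FPKM + 1), as deposited) in the 32 gene lists tested (y axis, with the genes tested), with a black line at each list median and a dashed line at the median of all genes, 0.59. Lists past the camera test are blue and the others grey, and the medians run from -1.99 for zinc and copper homeostasis to 3.23 for ribosome biogenesis.

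Markers of cell form did not move as 1 group. Of 19 hypha-associated genes, 8 were higher and 9 lower, 7 and 11 after scaling, and the list did not pass (adjusted p = 0.118). ECE1, which encodes the precursor of candidalysin, rose from 91.6 ± 7.01 to 385.9 ± 20.1 FPKM and the adhesin gene ALS3 from 165.5 ± 12.3 to 410.0 ± 34.9 FPKM, whereas the adhesin gene HWP1 fell from 442.0 ± 44.2 to 140.7 ± 10.9 FPKM (SD, n = 3). These 3 kept their direction under every scaling run. Of 6 yeast-form and white-cell markers, 3 were lower and 1 higher, and 5 and 1 after scaling (adjusted p = 0.0330, and adjusted p = 0.428 with an estimated correlation). The lower genes were WH11, RHD3 with -3.66 ± 0.073 and NRG1, a repressor of hyphal growth, with -1.62 ± 0.078, and RHD1, named after its value was seen, was higher. This call was lost after median-ratio scaling (adjusted p = 0.163), after quantile normalization (adjusted p = 0.118), with a filter at 10 FPKM (adjusted p = 0.0519) and without control library 2 (adjusted p = 0.0573), in a range from 0.0180 to 0.163 over the alternatives with the preset correlation. Of 8 opaque-cell markers, 5 were higher and 3 lower, and 4 and 3 after scaling (adjusted p = 0.603).

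Genes of known antifungal targets and drug transport gave a mixed picture. Of 24 ergosterol biosynthesis genes, 13 were higher and 6 lower, and after median-ratio scaling 7 were higher and 14 lower, and the list did not pass (adjusted p = 0.723). ERG6 rose from 68.8 ± 5.92 to 366.1 ± 15.3 FPKM (SD, n = 3). ERG11, the target of azoles, stood at 260.3 ± 20.5 and 416.6 ± 5.51 FPKM, which is 0.094 ± 0.073 above the median gene, and its call ended after median-ratio scaling (adjusted p = 0.235, in a range from 8.87e-07 over the alternatives). ERG1 stood at 198.2 ± 17.0 and 193.9 ± 7.26 FPKM (adjusted p = 0.739) and ERG3 at 44.4 ± 5.87 and 44.3 ± 3.62 FPKM (adjusted p = 0.982), and both were called lower after median-ratio scaling and after quantile normalization. The regulator gene UPC2 stood at 20.9 ± 1.23 and 27.1 ± 1.79 FPKM, called higher as deposited and lower after median-ratio scaling and after quantile normalization. Of 22 drug efflux and drug response genes, 12 were higher and 10 lower, and 7 and 11 after scaling (adjusted p = 0.117). The efflux pump genes CDR1, at 420.0 ± 72.0 and 1375 ± 54.3 FPKM, CDR2, at 63.2 ± 25.1 and 180.3 ± 15.6 FPKM, and MDR1, at 7.85 ± 0.525 and 42.2 ± 4.55 FPKM, rose under every scaling run. Among the 10 lower genes, CDR4 fell from 465.4 ± 12.1 to 16.8 ± 0.835 FPKM and TPO3 from 4806 ± 256 to 306.4 ± 20.3 FPKM. CDR4 and TPO3 were named after their values were seen. The glucan synthase gene GSC1, the target of echinocandins, rose by 0.31 ± 0.073 relative to the median gene.

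The calls of HSP90, HSP21 and the reference gene ACT1 depended on the scaling. HSP90 stood at 1433 ± 151 and 2441 ± 87.2 FPKM (SD, n = 3) and HSP21 at 594.3 ± 145 and 835.2 ± 124 FPKM, both called as deposited and neither after median-ratio scaling (adjusted p = 0.173 and adjusted p = 0.672). Without compound 20 replicate 2 the call of HSP21 was lost (adjusted p = 0.0590). Over the alternatives the adjusted p of HSP90 ran from 5.48e-07 to 0.173 and that of HSP21 from 0.00341 to 0.672. ACT1, the actin gene, stood at 1563 ± 81.4 and 1822 ± 84.0 FPKM, called higher as deposited and lower after median-ratio scaling and after quantile normalization, and it was not called without control library 3 (adjusted p = 0.0619, in a range from 7.34e-04 to 0.166). AOX2, an alternative oxidase gene, fell from 5982 ± 197 to 490.7 ± 19.0 FPKM under every scaling run. Of 22 heat shock and chaperone genes, 12 were higher and 7 lower, and 5 and 14 after scaling (adjusted p = 0.368).

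The other lists did not pass the camera test. In the proteasome list, 22 of 26 genes were higher and 3 lower, which turned to 6 and 13 after median-ratio scaling. In the respiratory chain and ATP synthase list, 21 of 29 were higher and 2 lower, and 13 and 7 after scaling, and this list passed after quantile normalization (adjusted p = 0.0101, in a range up to 0.493 over the alternatives with the preset correlation). Tricarboxylic acid cycle genes numbered 12 higher and 7 lower of 21, and 9 and 10 after scaling. For cell wall synthesis and remodelling, 22 of 37 were higher and 10 lower, and 17 and 15 after scaling. Heme biosynthesis gave 5 higher and 1 lower of 7, then 5 and 2, and lipid synthesis 18 and 5 of 24, then 12 and 8. In nitrogen, amino acid and peptide uptake, 19 of 31 were higher and 9 lower, then 16 and 11. Phosphate acquisition gave 6 higher and 4 lower of 14, then 3 and 9, and cell division 11 and 7 of 20, then 7 and 10. Of 16 osmotic stress, trehalose and glycogen genes, 7 were higher and 9 lower, then 5 and 10, and the list passed without control library 3 (adjusted p = 0.0483, in a range up to 0.223 over the same alternatives). Secreted hydrolases gave 11 higher and 8 lower of 26, then 8 and 12, and calcium signalling 11 and 1 of 14, then 7 and 5. The adjusted p-values of these 12 lists lay between 0.0593 and 0.849. Autophagy, with 3 genes of which 2 were higher and 1 lower as deposited, was too small to test.

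Across the 32 lists, 15 passed the camera test, 6 higher and 9 lower, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.175 and 7 lists had an unadjusted p below 0.05. With fry 29 lists passed. The counts of called genes adjusted over the list alone equalled those over all genes in 32 of the 33 lists, the exception being glycolysis and fermentation, with 3 higher genes in place of 2. Median, mean and test differed in sign for some lists. The ergosterol, opaque, tricarboxylic acid cycle, phosphate, cell division and secreted hydrolase lists had a median and mean above 0 and a camera direction down. The drug efflux and heat shock lists had a median above 0, a mean below 0 and a camera direction down, with a fry direction of down for the first and up for the second. The hypha list had a median and mean below 0, a camera direction down and a fry direction up.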

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

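The number of called genes stayed between 4652 and 5076 over all alternatives, and the number with a 2-fold change between 2338 and 2881. Leaving out 1 library gave 4891 to 4967 called genes, 2714 to 2799 with a 2-fold change, 69.9% to 71.6% higher and 14 to 16 lists. The share of called genes that were higher, 70.8% as deposited, was 67.1% after scaling to the same total, 49.99% after median-ratio scaling and 50.2% after quantile normalization, as centring on the median gene brings about. The 15 lists past the camera test became 0 with an estimated correlation and 29 with fry, which does not set a list against other genes. The list call of yeast-form and white-cell markers was the one most often lost.

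Of the 72 named genes, 65 kept their direction and side of the threshold under all 16 alternatives. The log2 changes in this paragraph are those fitted under each alternative, without subtraction of the median of 0.59. ERG3 changed sign to -0.11 after scaling to the same total, -0.58 after median-ratio scaling, -0.50 after quantile normalization and -0.084 with array weights, and lay between -0.11 (without control library 2) and 0.074 without 1 library. UPC2 turned to -0.21 and -0.29 after median-ratio scaling and quantile normalization, ACT1 to -0.38 and -0.33, and HSP21 to -0.088 after the first. ERG1 lay between -0.092 and 0.031 without 1 library. Calls were also lost for HSP21 with robust moderation and for ACT1 after scaling to the same total. Among lists, the direction changed at an adjusted p of 0.901 for nitrogen, amino acid and peptide uptake with the filter at 10 FPKM, 0.455 for the proteasome after median-ratio scaling and 0.453 for the tricarboxylic acid cycle after quantile normalization. With fry it changed at an adjusted p of 0.00342 for ergosterol biosynthesis, 0.00879 for hypha-associated genes, 0.0523 for opaque-cell markers, 0.507 for heat shock proteins, 0.00125 for the tricarboxylic acid cycle, 0.517 for phosphate acquisition, 0.00103 for cell division and 0.00241 for secreted hydrolases. Fry tests a list against 0, while camera sets it against the other genes, and the median of all tested genes was 0.59. The ergosterol, opaque, tricarboxylic acid cycle, phosphate, cell division and secreted hydrolase lists had mean changes from 0.20 to 0.50. These lie above 0 and below 0.59, so opposite directions can follow from what each test compares with. Beyond this and what the scalings do by construction, the cause was not tested. No paired analysis was possible because the descriptions of all 3 control samples name the same column, so no control column can be tied to a sample and its replicate number, although the column names of both groups run from 1 to 3. Count tests were not run, since the table holds no counts. Without depth, no limit for low genes can be given.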

Other observations

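All tests in this part were chosen after the results were seen. So were its genes, apart from those of the naming rule and the fixed lists used as a whole. Genes that share the letters of their symbol were grouped into 101 families of at least 5 tested genes and tested with camera. Of these, 12 families passed as deposited and 21 after median-ratio scaling, 11 of them under both, and 0 passed with an estimated correlation. PLB passed only as deposited (adjusted p = 0.0653 after scaling). As deposited TIM was the 1 family past the test with no gene in a fixed list, and after scaling there were 5, namely TIM, TIF, RPC, CCT and GCD. The TIM genes encode parts of the machinery that imports proteins into mitochondria, and 11 of 12 were higher with compound 20, with a median log2 change of 1.42 relative to all genes (adjusted p = 0.0265, and adjusted p = 0.681 with an estimated correlation). TIM44 rose from 52.4 ± 3.51 to 383.2 ± 10.1 FPKM (SD, n = 3), and TIM12 was the 1 not called. After median-ratio scaling 11 TIM genes were higher and 1 lower. The GAL family had 4 of 5 genes lower (adjusted p = 0.0185, and adjusted p = 0.563 with an estimated correlation), and all 5 after median-ratio scaling. GAL1, GAL10, GAL7 and GAL102 were the lower ones, while GAL4, a regulator that also stands in the glycolysis list, was higher as deposited. The TIF genes of translation initiation, 7 of 7 higher, did not pass as deposited (adjusted p = 0.0527, and adjusted p = 0.623 with an estimated correlation) and passed after scaling (adjusted p = 0.0149).

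More genes were called higher than lower with compound 20. The tables argue against the loss of a few abundant transcripts as the whole of it. With libraries scaled to the same total, the median log2 change was 0.48. Leaving the 20 most abundant genes out of the totals lowered it to 0.28, and to 0.22 to 0.33 without any 1 library. These 20 were ranked on their mean over all libraries, so genes that rose with compound 20 could be among them. An extra chromosome copy in 1 group is argued against by the medians per chromosome, which lay no further than 0.12 from that of all genes, where 1 extra copy of 2 would give 0.58. A change in total mRNA per cell may underlie the median of 0.59 and cannot be told apart from the scaling of the libraries, since no spike-in was analysed here.

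Ribosome genes were higher and genes of alternative carbon use lower. The scaling of the libraries is argued against as the cause, because all 65 ribosome biogenesis genes stayed higher after median-ratio scaling. Exhaustion of glucose in the control cultures may have been expected to raise the alternative-carbon genes there and to lower glycolysis, but 17 of 20 glycolysis genes were higher in the controls, which argues against it as the sole cause. A different growth stage of the cultures cannot be told apart from the effect of compound 20: histone and DNA replication genes moved with the group, with a median log2 change of 1.76 as deposited, and no growth data were analysed here. An effect of compound 20 itself stays among the open explanations.

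Copper-related genes did not all move one way as deposited. A set of 10 copper and iron genes was chosen after values were seen, although the naming rule also covers CTR1, FRE7 and SOD3. It leaves out iron genes such as FTR2 and FRE10, which were called higher as deposited and after median-ratio scaling. Of the 10 genes in the set, 6 were called lower and 4 higher as deposited, and 7 lower and 0 higher after median-ratio scaling. Lower under both were the transporter gene CTR1, the reductase gene FRE7, the regulator gene MAC1, CCC2, CRP1, and SOD3, which replaces a copper enzyme when copper is scarce. FTR1 (0.28), FET3 (0.58), CTR2 and SOD1 were called higher as deposited, and of these FTR1 was called lower after scaling. Relative to the median gene, FTR1 lay at -0.30 and FET3 at -0.0086. CTR2, another copper transporter gene, changed by 0.54 as deposited and lay at -0.041 relative to the median gene. More copper in the cells with compound 20 could underlie the lower genes and could be expected to raise the copper exporter gene CRP1, which changed by -0.28 as deposited and by -0.87 relative to the median gene, and 1 gene does not exclude the explanation. SOD1, the copper enzyme, rose by 0.56 as deposited and lay at -0.022 relative to the median gene.

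The 6 libraries can be split into groups of 3 in 10 ways, which is too few for a share under 0.05. The real split gave 5018 genes past the adjusted p and 2764 with a 2-fold change, and the highest of the other splits gave 0 and 0 with limma, with at most 18 genes at an unadjusted p below 0.05 against 5043 in the real one. For lists, the real split gave 15 and the others between 12 and 19, so that 4 of the 10 splits gave at least 15. Every other split puts treated and control libraries together in each group, so the real difference enters its residual spread. Its low gene counts were therefore given in advance and do not measure chance. Such a split also keeps part of the real group difference, so its list count is no chance level either.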
